A study of Mus musculus with 152 samples.

How the data were processed

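Gene expression was measured in whole blood of mice injected with a solution of caesium-137 chloride, a radioactive salt that spreads through the body and irradiates it from within. Per the labels, the injected activities were 0, 158, 191, 215 and 259 µCi, and blood was taken on day 2, 3, 5, 7 or 14. Per the labels' protocols, RNA came from PAXgene blood tubes, globin transcripts were depleted, and samples were kept when an electrophoretic RNA integrity number passed a set minimum. Each RNA was labelled with Cy3 and hybridised alone to an Agilent array. Scanned images were read with Agilent Feature Extraction 10.7, per the submitters' processing notes.

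The deposited values were log2 intensities in 1 table of 152 arrays and 15008 features. The scale was inferred from the values, which ran from -0.79 to 20.72 with array medians between 5.08 and 5.62. The background correction, the normalization, the filter that left these features and the rule behind blank values are not given in the sources used here. Whether the deposited values were scaled between arrays therefore stays unknown. The smallest standard deviation of a probe over all arrays was 0.41 on the log2 scale. Of the features, 14967 were probes and 41 were spike-in, corner and other control features, which stayed out of every test. Blank cells made up 3.82% of the probe values, and no probe was blank on more than 39 arrays (25.7%). Blanks were left out probe by probe and not filled. No pair of arrays held identical values, and the highest correlation between 2 arrays was 0.9894.

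The files do not pair probes with genes. Results are therefore given per probe, 0 of the 25 gene lists fixed beforehand were run, and probe identifiers are printed for 2 probes that rose and 2 that fell. The rule fixed beforehand took, for each day, the 10 probes with the highest and the 10 with the lowest log2 difference among those called and moved in the same direction at all 4 activities. The 2 leading probes in each direction on day 14 are named, and the others are summarised. The plan for 1 probe per gene was replaced by a test of every probe.

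Samples were grouped by activity and day from their titles, which gave 25 groups of 6 mice, with 7 mice at 191 µCi on day 2 and at 215 µCi on day 7. The source names of the day 7 samples state day 2, against their titles and characteristics, and the titles were followed. The labels speak of replicate mice, and each mouse gave 1 array. The number of arrays limits the precision.

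Differences were tested in R 4.3.3 with limma 3.58.1 on the log2 values. A mean was fitted for each of the 25 groups over all 152 arrays, which left 127 residual degrees of freedom for a probe without blanks. Moderated tests were two-sided, with Benjamini-Hochberg adjustment over the probes of each comparison, and a probe was called at an adjusted p under 0.05. For each day, the mean of the 4 injected groups was set against the control group of that day, and each activity was set against the same controls. Activity trends were slopes over the 4 injected groups, in log2 units per 100 µCi. Further tests asked whether the injected minus control difference changed between days (a moderated F test), whether it differed between day 14 and day 2, and whether the control groups differed across days. In all, 34 counts of called probes were made. The largest absolute difference of a moderated t from limma's own fit was 8.9e-14.

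The tests were first run on simulated data with 200 changed probes among 14967, drawn with each probe's own spread. For injected against control mice on day 14, 87.9% of probes changed by 2 log2 units were called, 52.2% of those changed by 1 and 10.4% of those changed by 0.5, with 4 unchanged probes called. For 259 µCi against control on day 14 the shares were 80.3%, 25.4% and 1.49%. For the activity trend on day 14, slopes of 2, 1 and 0.5 per 100 µCi were called in 80.3%, 28.4% and 1.49% of probes. The simulated arrays held no clusters, and far fewer probes changed than were called in the same comparisons of the real data. The adjustment is stricter when few probes change, so these shares may lie below those of the real data.

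The arrays were also examined for technical structure. Principal components were computed from the 7942 probes without blanks. On principal components 2 and 3, which held 17.1% and 11.4% of the variance, Ward clustering parted the arrays into 3 clusters of 96, 33 and 23 arrays. The clusters cut across most of the study's groups. The E1A spike-ins, which carry no mouse RNA and were not used to form the clusters, differed between them. The brightest of them averaged 17.49 ± 0.61 (SD, n = 96), 15.86 ± 0.64 (SD, n = 33) and 16.35 ± 0.48 (SD, n = 23) log2 units, with a permutation p of 1e-05, the smallest that 100000 resamples can give. The clusters were therefore treated as a technical batch, and values within clusters and with the cluster as a block are given.

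The alternatives fixed before the data were examined were quantile normalization, a common array median, a filter on dim probes, the replicate block, array weights, the trend and robust options of eBayes, fits to fewer arrays, pooled controls, a fit without day 7 and slopes that include the controls. Alternatives with the array clusters, other treatments of blanks, and each 191 µCi array left out in turn on days 2 and 3 were added after seeing the data.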

Results

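The series measured blood gene expression after injection of caesium-137, over 4 injected activities and a control, each sampled on 5 days. There were 152 one-colour arrays, 122 from injected and 30 from control mice. Each group of 1 activity and 1 day held 6 mice, except 191 µCi on day 2 and 215 µCi on day 7, which held 7. Values are deposited log2 intensities of 14967 probes. The median standard deviation within groups was 0.6 log2 units, and the median correlation between arrays was 0.952 within groups and 0.932 between groups. Between 15 and 2644 probes were blank on an array.

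Arrays also fell into 3 clusters that cut across most groups. Some groups lay mostly in 1 cluster: at 191 µCi on day 7 the clusters held 0, 5 and 1 arrays, against 4, 2 and 0 of the controls of that day, and at 215 µCi on day 5 all 6 were in the largest. Controls were unevenly spread over them: on day 14 the clusters held 2, 1 and 3 of the 6 controls, and on day 2 all 6 controls were in the largest cluster. Counts within clusters are therefore given beside the pooled counts.

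**Figure D1:**
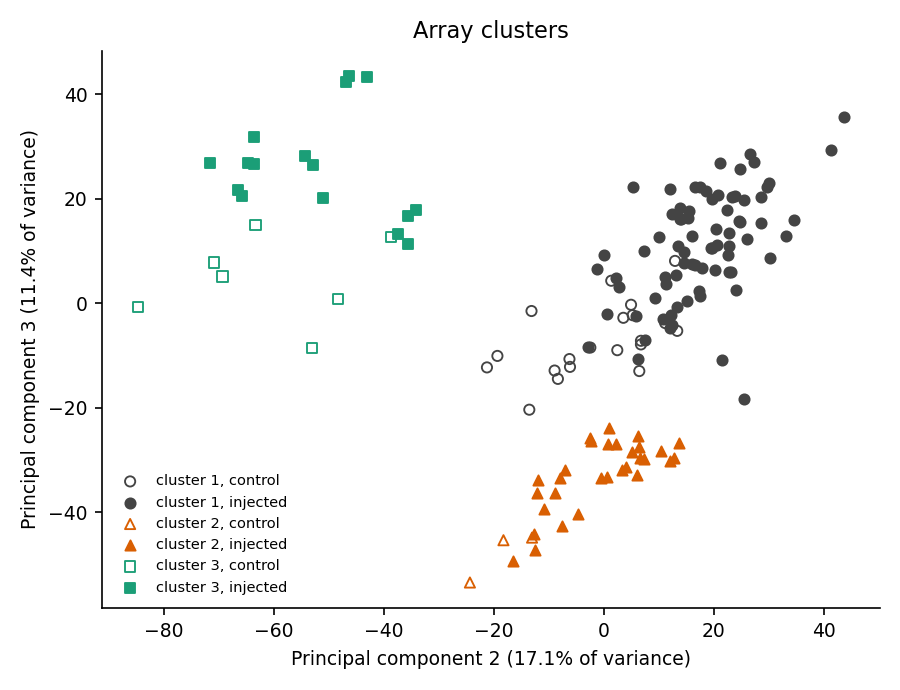
Each point is 1 of the 152 arrays, placed by its score on principal component 2 (17.1% of variance, x axis) and principal component 3 (11.4%, y axis), filled for injected and open for control mice. The 3 symbols mark clusters of 96, 33 and 23 arrays, and each holds injected and control mice.

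The first comparison asked how blood of injected mice, averaged over the 4 activities, differed from that of control mice on the same day. Probe A_51_P246317 rose on every day. It averaged 4.38 ± 0.45 (SD, n = 6) in controls and 7.75 ± 0.68 (SD, n = 24) in injected mice on day 14, and the lowest injected mouse, at 6.18, lay above the highest control, at 4.98. Its difference grew from 1.81 ± 0.24 (SE) log2 units on day 2 to 2.27 ± 0.25 on day 3, 2.95 ± 0.25 on day 5 and 3.45 ± 0.24 on day 7, and was 3.36 ± 0.25 on day 14, a 10.3-fold increase (limma adjusted p = 4.9e-23). Probe A_66_P111660 followed a like course, with 1.66 ± 0.25 on day 2, 3.50 ± 0.25 on day 7 and 3.28 ± 0.25 on day 14 (limma adjusted p = 3.51e-22). All 24 injected mice of day 14 lay above the controls on this probe as well, at 7.17 or more against 5.83 or less.

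Probe A_55_P2117614 fell on every day, from 8.14 ± 0.50 (SD, n = 6) in controls to 4.92 ± 0.79 (SD, n = 23) in injected mice on day 14. Its differences were -1.15 ± 0.30 (SE) on day 2, -2.15 ± 0.30 on day 3, -2.27 ± 0.30 on day 5, -2.47 ± 0.30 on day 7 and -3.21 ± 0.30 on day 14, a 9.25-fold decrease (limma adjusted p = 5.02e-16). Probe A_55_P2123491 moved likewise, by -1.47 ± 0.29 on day 2 and -3.19 ± 0.30 on day 14 (limma adjusted p = 2.11e-16). On day 14 this probe was blank in 4 of the 24 injected mice, and the 20 measured ones reached 4.62 at most, against 5.68 or more in controls. If blanks stand for low signal, leaving them out makes the estimated decrease of this probe too small. It was -3.22 with blanks filled by the 1st percentile of the array, and ran from -3.43 to -2.98 over the alternatives. With the array cluster as a block, the 4 probes differed by 3.25, 3.28, -2.94 and -3.07 on day 14.

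**Figure D2:**
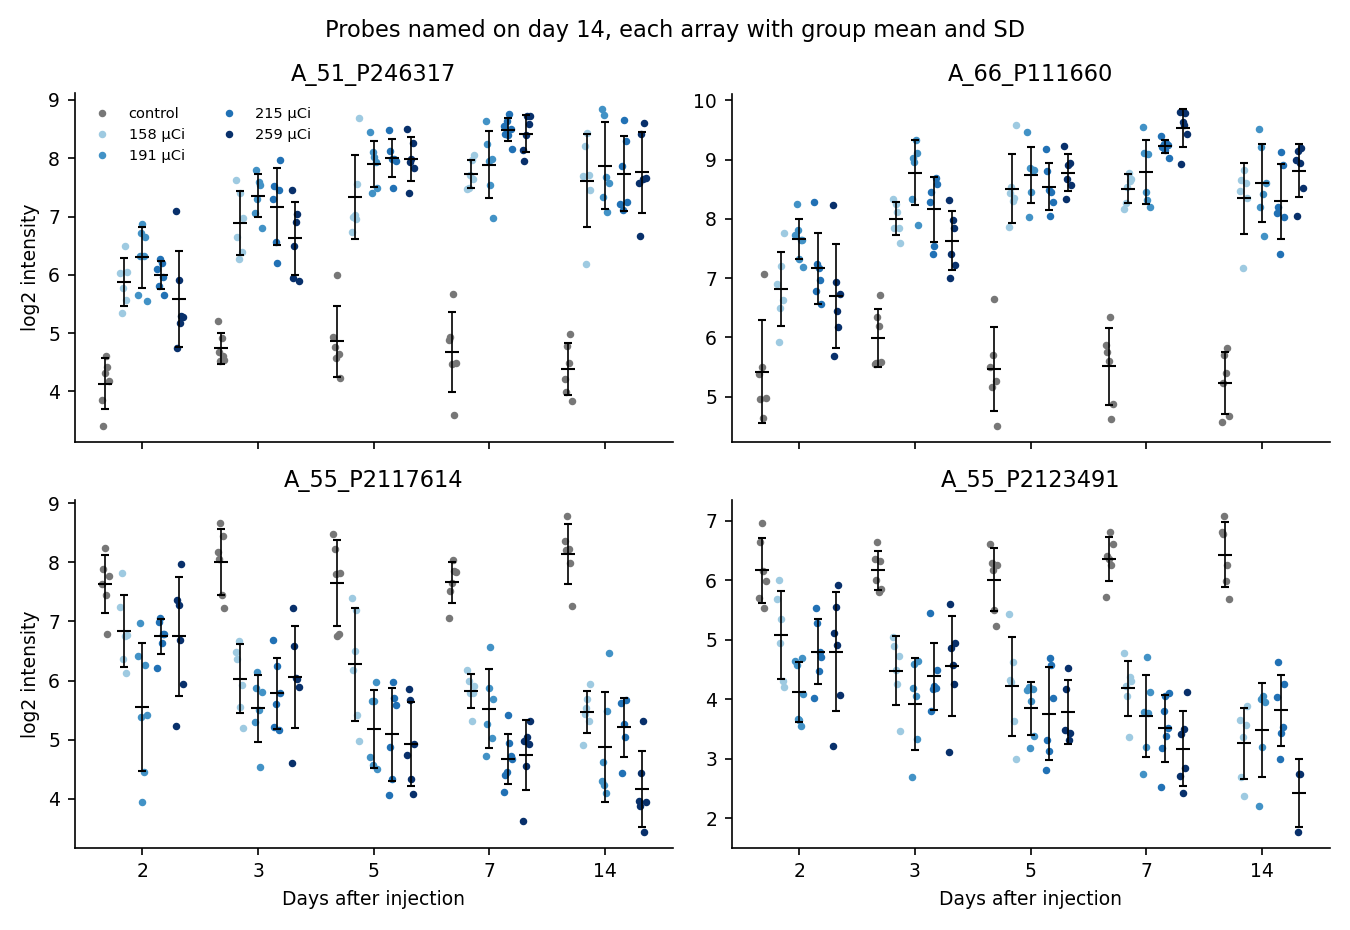
Each panel shows 1 probe, with log2 intensity on the y axis and days after injection on the x axis; points are arrays, coloured by injected activity, and bars are the group mean and SD. On day 14 every injected array of A_51_P246317 and A_66_P111660 lay above, and every measured injected array of A_55_P2117614 and A_55_P2123491 below, the 6 controls of that day.

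Many probes differed between injected and control mice on each day. On day 2, 5530 of 14967 tested probes were called, 2296 higher and 3234 lower in injected mice. The counts were 6235 on day 3 (2796 higher, 3439 lower), 6771 on day 5 (3009 higher, 3762 lower) and 6834 on day 7 (2769 higher, 4065 lower). Day 14 had 9251, which was 61.9% of those tested, with 4442 higher and 4809 lower. At least 2-fold differences were called in 1868, 2248, 1918 and 2301 probes on days 2, 3, 5 and 7, and in 5340 on day 14. The median absolute difference of the called probes was 0.87 log2 units on day 2 and 1.07 on day 14.

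The balance of directions depended on the scaling of the arrays. After a shift to a common median, the calls were 2676 higher and 2488 lower on day 2, 3774 and 2367 on day 3, 3800 and 3178 on day 5, and 4012 and 3178 on day 7. After quantile normalization, day 14 had 3050 higher and 5056 lower. Within clusters, each fit held only the arrays of 1 cluster and 1 day, with the activities pooled. In the largest cluster, 5582 probes were called on day 2 (18 injected, 6 control mice), 5601 on day 3 (14 and 4), 1587 on day 5 (16 and 4), 7894 on day 7 (12 and 4) and 3172 on day 14 (16 and 2). The cluster of 33 arrays gave 2256 on day 7 (12 and 2). In the cluster of 23 arrays, 7136 were called on day 5 (4 and 2) and 8014 on day 14 (5 and 3). On day 3 that cluster (2 and 2) had 0 calls in limma and 2231 probes at an unadjusted p under 0.05. In the probes of the pooled calls, which include these arrays, the median ratio of the difference within a cluster to the pooled one ran from 0.81 to 1.11, and was 0.86 where 0 were called. The other pairs of cluster and day held fewer than 2 controls. With the array cluster as a block, 5331 of the 5530 pooled calls of day 2 stayed called in the same direction. So did 5302 of 6235 on day 3, 6599 of 6771 on day 5, 6796 of 6834 on day 7 and 8879 of 9251 on day 14.

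The probes called on different days overlapped, and each day had its own controls. All days shared 1 estimate of the spread per probe, so some overlap beyond that of independent lists is built in. On all 5 days, 413 probes were called higher and 1956 lower, against 4.73 and 16.3 for independent lists. With a common median these numbers were 711 and 1187, and with quantile normalization 309 and 1472. Quantile normalization kept 203 of the 413 and 1374 of the 1956. Between days 7 and 14, 2099 probes were higher and 3668 lower on both days, against 822 and 1305 for independent lists, and 4 were called in opposite directions. Between days 2 and 14, 966 were higher and 2706 lower on both, against 682 and 1037, and 174 had opposite directions, against 1696 for independent lists. The number with opposite directions was 283 after quantile normalization and 142 with a common median. Across probes, which are not independent replicates, the differences of day 14 correlated with those of day 2 at r = 0.62 and with those of day 7 at r = 0.85. No call was made on any day for 2925 probes.

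The size of the difference varied with the intensity of the probe. Probes were divided into 10 equal groups by mean intensity. On day 14, the median difference was 0.67 log2 units in the brightest group, -0.50 in group 6 and 0.64 in the dimmest. On day 2 the same values were 0.28, -0.24 and 0.10. In the dimmest group 23.7% of the values of injected mice and 4.06% of those of controls were blank on day 14, and with blanks filled by the 1st percentile of the array its median difference was 0.53. In probes with a mean above 12 the median difference of day 14 was 0.83, and -0.01 after quantile normalization.

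**Figure D3:**
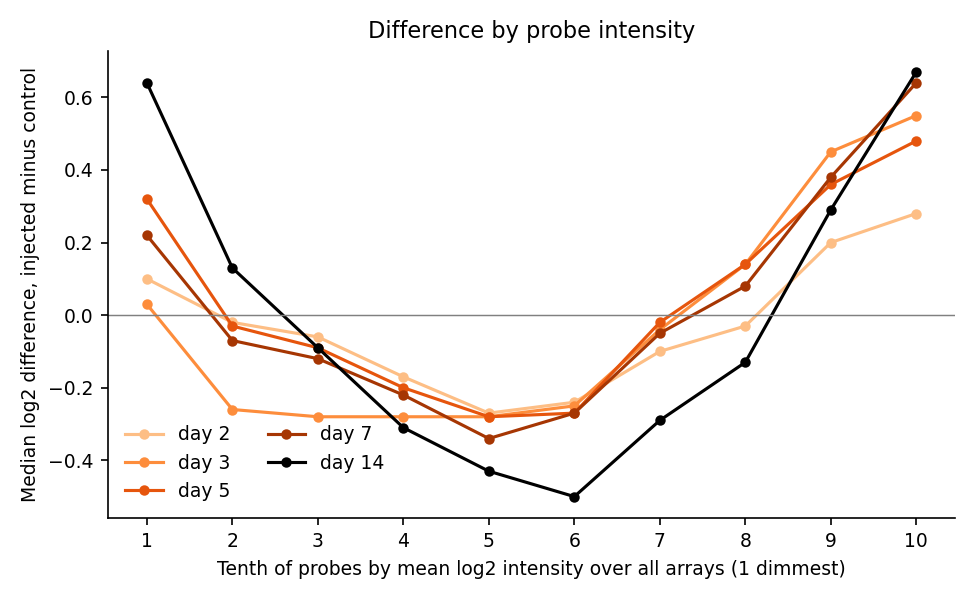
The y axis gives the median log2 difference, injected minus control, and the x axis 10 equal groups of probes ordered by mean log2 intensity over all arrays, with a line for each day. On day 14 the line ran from 0.64 in the dimmest group through -0.50 in group 6 to 0.67 in the brightest.

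Each activity was then compared with the controls of its day. At 158 µCi, 2445 probes differed on day 2, 2585 on day 3, 2708 on day 5, 2721 on day 7 and 7048 on day 14. At 191 µCi the counts were 6669, 7569, 3741, 6346 and 6280. For 215 µCi they were 1698, 2769, 5525, 4859 and 6487, and for 259 µCi 3203, 3427, 5324, 5112 and 9255. The counts did not follow the order of activities on any of the 5 days, although on day 5 they did so after quantile normalization, without the dimmest 25% of probes, with the array cluster as a block and among probes without blanks, and on day 14 in the largest cluster. In the fit to all arrays 191 µCi had the largest count on days 2, 3 and 7. On day 7 it was 6969 with the array cluster as a block, against 6384 at 259 µCi. Of the 6346 calls at 191 µCi on day 7, the block kept 5293 in the same direction. On day 14 the largest count was that of 259 µCi, with 4600 probes higher, 4655 lower and 7334 at least 2-fold. With array weights 158 µCi had more on that day, 8699 against 8593. Probe A_55_P2117614 differed on day 14 by -2.67 ± 0.38 (SE) at 158 µCi, -3.27 ± 0.38 at 191 µCi, -2.93 ± 0.40 at 215 µCi and -3.97 ± 0.38 at 259 µCi. Probe A_51_P246317 differed by 3.23 ± 0.31, 3.49 ± 0.31, 3.35 ± 0.31 and 3.38 ± 0.31 in the same order. A common median moved the share of higher calls by over 10 percentage points in 13 of these 20 comparisons and quantile normalization in 4. Many of these counts depended on the model. Over the alternatives planned beforehand, those at 158 µCi ran from 1177 to 2647 on day 2, 2083 to 5740 on day 3, 836 to 7582 on day 5 and 2055 to 6670 on day 7. At 191 µCi they ran from 853 to 7297 on day 5 and 5542 to 10051 on day 7, and at 215 µCi from 1440 to 4416 on day 2, 1393 to 4819 on day 3 and 3448 to 7899 on day 7. At 259 µCi they ran from 2104 to 3430, 2809 to 5401, 4221 to 8061 and 4082 to 7982 on days 2, 3, 5 and 7. With the array cluster as a block, the count became 2806 at 215 µCi on day 2 and 4710 at 158 µCi on day 7. In the largest cluster alone, it became 30 at 158 µCi and 212 at 191 µCi on day 5.

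**Figure D4:**
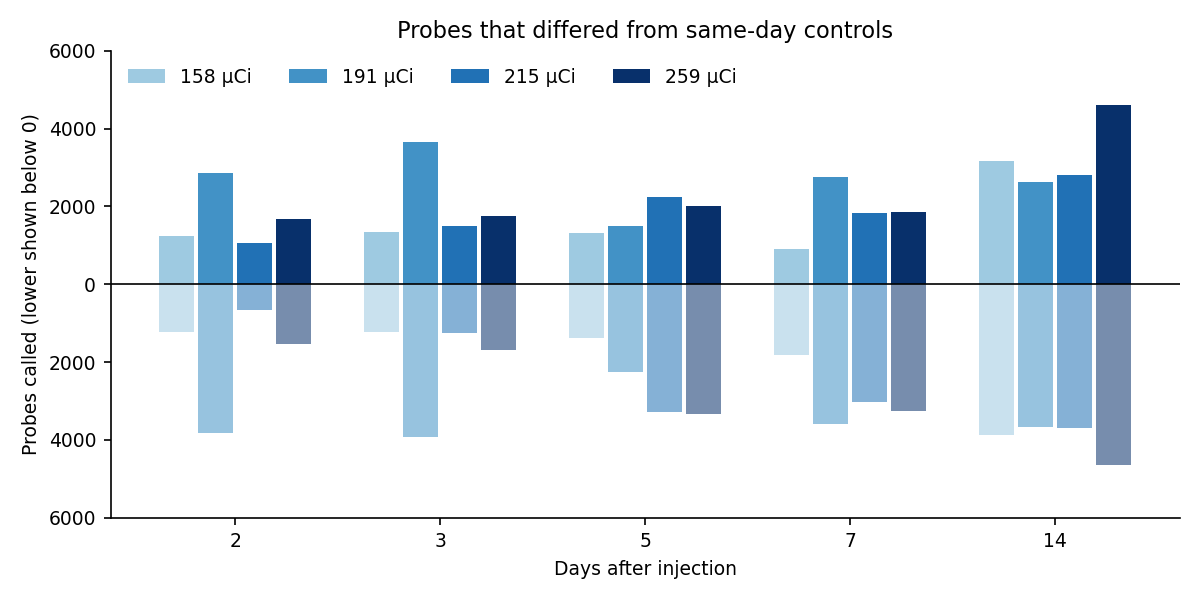
Bars give the number of probes called in limma against the controls of the same day, higher above the 0 line and lower below it, for each injected activity, with days after injection on the x axis. The tallest pair of bars is that of 259 µCi on day 14, with 4600 probes higher and 4655 lower.

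Whether the response scaled with the injected activity was tested as a slope over the 4 injected groups. On day 14, 2895 probes had a slope, 1170 rising and 1725 falling with activity. The probes that fell had median differences from control of -0.85 at 158 µCi, -0.85 at 191 µCi, -1.06 at 215 µCi and -1.89 at 259 µCi, and 1456 of them were also called lower in injected mice as a whole, a test that shares these arrays. Those that rose had medians of 0.01, 0.13, 0.46 and 1.05. Of these, 503 were also called higher, 78 were called lower and 589 were not called. Independent lists would give 347 rising and 554 falling probes called in the same direction. Both sets were picked for their slopes over these groups, so a rise or fall of their medians with activity is built in. Probe A_55_P2117614 fell by 1.17 ± 0.37 (SE) per 100 µCi on day 14 over 23 measured mice (limma adjusted p = 0.015). The slope of A_51_P246317 was 0.09 ± 0.30 (limma adjusted p = 0.886). With the array cluster as a block, 3541 probes had a slope on day 14, and in the largest cluster alone 1693.

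In limma, 0 probes had a slope on day 2 (401 at an unadjusted p under 0.05) and 0 on day 5 (2765 at an unadjusted p under 0.05). Array weights gave 1 on day 2 and 5231 on day 5, more than the 2679 they gave on day 14. Day 3 had 112, of which 11 rose and 101 fell, and 0 when only the arrays of that day were fitted. With a common median, 8 probes rose and 25 fell on day 3. Day 7 had 3, all rising, with slopes of 0.94 to 4.33 per 100 µCi. When only the arrays of day 7 were fitted, 9 rose and 63 fell, and with array weights 13 rose and 6 fell. Over all days together, 1301 probes rose and 1503 fell with activity, and after a common median 1578 rose and 833 fell.

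The time course was tested on the injected minus control difference itself. It varied between days in 2006 of 14951 probes, and in 3429 with the array cluster as a block. From day 2 to day 14 it increased in 1171 probes and decreased in 1826. Quantile normalization gave 715 and 2333. With the array cluster as a block, 2292 of the 2997 calls of the main fit stayed called in the same direction. All 6 controls of day 2 lay in the largest cluster, against 2 of the 6 controls of day 14. Of the 1171 that increased, 1080 were called higher on day 14. The median difference of the 1171 was -0.10 on day 2, 0.35 on day 3, 0.44 on day 5, 0.73 on day 7 and 1.12 on day 14. Of the 1826 that decreased, 1201 were called lower on day 14. The medians of the 1826 ran from 0.02 on day 2 through -0.17, -0.37 and -0.48 to -1.08 on day 14. Among the 1826, 414 had already been called lower on day 2 and 737 had been called higher. Of these 737, 578 were not called on day 14 and 122 were called lower. Of the probes that were lower on all 5 days, 377 of 1956 decreased further by day 14, while of the 413 that were higher on all days 11 increased further and 28 decreased. The 4 named probes were chosen for their differences on day 14, which favours a growth up to that day. Their changes from day 2 were 1.56 ± 0.35 (SE) for A_51_P246317, 1.61 ± 0.35 for A_66_P111660, -2.06 ± 0.43 for A_55_P2117614 and -1.72 ± 0.41 for A_55_P2123491. With the array cluster as a block they were 1.37, 1.62, -1.63 and -1.48 in the same order. The largest cluster alone gave 1312 probes for this difference.

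Control mice were compared across the 5 days as a background for time alone. In limma, 0 probes differed between the control groups, with 1357 at an unadjusted p under 0.05, and array weights gave 1570. Probe A_51_P246317 averaged 4.13 ± 0.43 (SD, n = 6), 4.74 ± 0.27, 4.86 ± 0.61, 4.68 ± 0.69 and 4.38 ± 0.45 in controls of days 2, 3, 5, 7 and 14 (limma adjusted p = 0.669).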

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

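The tests that use the array clusters, leave out 1 array at 191 µCi, exchange arrays for the differences between days or weight the arrays for the ratios at 191 µCi were chosen only after the result was seen.

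In 9 of 149 groups of 4 to 7 values, 1 mouse stood far from the rest of its group, where chance gives about 1 in 20, or 7.45. Blank probes numbered 1089 in control replicate 2 of day 2 (next 405), 712 at 158 µCi on day 2 in replicate 3 (next 250), 1896 at 191 µCi on day 5 in replicate 3 (next 686) and 210 at 215 µCi on day 7 in replicate 2 (next 649). Array medians were 5.565 at 158 µCi on day 14 in replicate 6, 5.348 at 215 µCi on day 5 in replicate 3 and 5.444 at 259 µCi on day 5 in replicate 2, each the highest of its group. Probe A_66_P111660 was at 7.07 in control replicate 5 of day 2 (next 5.50) and at 7.17 in replicate 3 of 158 µCi on day 14 (next 8.35).

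The effect of injection differed between days in 2006 probes, and between day 14 and day 2 in 2997. For the splits, a difference from control that is the same on every day was removed, and arrays were exchanged within days. The other splits reached 44 and 847 probes at most. In both tests 1 of 100 splits, the real one, gave as many, which makes chance unlikely. These splits ignored the array clusters and say nothing about them. With the array cluster as a block, 2292 of the 2997 probes stayed called in the same direction. The named probes were chosen for their day 14 differences and so are no further evidence of a change between days. They changed by 1.56 (A_51_P246317), 1.61 (A_66_P111660), -2.06 (A_55_P2117614) and -1.72 (A_55_P2123491) log2 units between day 2 and day 14.

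Blank values, which no comparison used, were more frequent in injected mice on day 14, by 1022 probes per array (1125 ± 789.6, SD, n = 24, against 102.8 ± 70.37, SD, n = 6; permutation p = 0.00409, adjusted over 5 days 0.0204). On the other days the excess ran from -64.62 to 235.8, with adjusted p values of 0.3 or more. The array cluster did not cause it alone, since within the largest cluster the excess was 1286 (16 injected and 2 control mice, exact permutation p = 0.0196). In the smallest cluster, blank probes of day 14 numbered 15 to 297 in 5 injected mice and 34 to 58 in 3 controls. No excess of the pooled size was seen there. In the remaining cluster they numbered 399 to 1275 in 3 injected mice and 99 in 1 control. The size of the excess therefore differed between clusters. Of 1840 probes that were blank at least 25 percentage points more often in injected mice, 1829 had a difference on the arrays that kept a value, with a median of -0.60 (813 called lower, 106 higher), as a loss of signal in probes that fell would give. That median came from the fit without the array cluster, and 3 of the 6 controls were in the smallest cluster. How far the clusters added to it was not tested. Whether a loss of signal reflects the mice or the rule for blanks stays open.

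Bright probes were higher and mid-level probes lower in injected mice on day 14, by 0.83 and -0.19 at the median, a difference of 1.02 log2 units. E1A spike-ins of the same ranges of intensity, 3 bright and 3 mid-level, differed by 0.12 ± 0.09 (SE), which argues against a scanner or normalization curve that acts on every feature alike. With the array cluster as a block the difference was 0.84, which argues against the clusters. Quantile normalization lowered it to 0.25, but does so by its construction whatever the source. A change in the make-up of blood RNA after injection may underlie it; this was not tested.

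More probes were called at 191 µCi than at higher activities on days 2 and 3, by a factor of 2.08 and 2.21 over the larger count at 215 and 259 µCi. With the array cluster as a block the smaller of these ratios was 1.99, and with the 191 µCi array left out that lowered the count most it was 1.66, which argues against the clusters and against a single array of that group. With array weights the ratios were 1.44 and 1.71, so arrays of unequal quality are not excluded. The 191 µCi group differed from the mean of the other injected groups in 722 probes on day 2 and 1030 on day 3, and in 2170 and 2328 with the array cluster as a block. A response that does not follow the injected activity, or an unrecorded difference in how this group was handled, may explain it, and neither was tested.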

How the results depend on the processing

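The alternatives with the array clusters, the filled blanks, the probes without blanks and the 191 µCi arrays left out in turn were chosen after seeing the data, and the others before the data were examined. All 34 counts stayed within 1.5 times their value under quantile normalization, without the dimmest 25% of probes, and with the eBayes trend and robust options. The single count run without day 7 did so as well. With the replicate block, made from the replicate number within day, all 33 counts that could be computed did so too, as with 9230 probes on day 14 and 2063 for the differences between days. The numbers did not pair the samples: 113 of 300 same-numbered pairs had correlated deviations above 0.1, against 554 of 1548 pairs with different numbers, and 28 of 152 arrays correlated best with an array of their own number. Over the alternatives, 267 of 268 values of the 4 named probes kept their direction and their side of the threshold. In the other one, A_55_P2123491 on day 14 minus day 2 fell by 1.52 on the log2 scale in the largest cluster, with an adjusted p of 0.0879 against 0.00117 in limma's main result, and fewer arrays were in that fit. Leaving out each 191 µCi array in turn gave 5316 to 7254 probes on day 2 and 6455 to 7437 on day 3. Gene list alternatives were not run, because probes were not paired with genes, and testing every probe was already the main result.

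Counts that moved by over 1.5 times are given by alternative; for those that only change weights, scale, reference or model terms, the cause was not tested. With arrays shifted to a common median, the counts were 33 and 1 for the activity trend on days 3 and 5. Weighting the arrays gave 5081, 7582 and 6670 at 158 µCi on days 3, 5 and 7, 10051 at 191 µCi on day 7, 4416 and 7899 at 215 µCi on days 2 and 7, 7982 at 259 µCi on day 7, 1, 1244, 5231 and 19 for the activity trend on days 2, 3, 5 and 7, 4575 for the trend over all days, 6348 for day 14 minus day 2, 6454 for the differences between days and 1570 for the controls across days. A fit to the arrays of 1 day gave 0 and 72 for the activity trend on days 3 and 7. Fits to the arrays of the 2 groups alone, fewer than in the joint fit, gave 1177, 836 and 4840 at 158 µCi on days 2, 5 and 7, 853 at 191 µCi on day 5, 1393 at 215 µCi on day 3 and 2104 at 259 µCi on day 2. Pooling the controls of all days, which gives more control arrays, yielded 10218, 11205 and 10576 for all injected mice on days 3, 5 and 7, 5740, 6775 and 5717 at 158 µCi on days 3, 5 and 7, 7297 at 191 µCi on day 5, 3156 and 4819 at 215 µCi on days 2 and 3 and 5401 and 8061 at 259 µCi on days 3 and 5. Slopes that included the controls at 0 µCi, and so the difference from control, gave 4781, 5190, 6961, 6593 and 9382 for the activity trend on days 2, 3, 5, 7 and 14 and 11565 for the trend over all days. The array cluster as a block gave 4710 at 158 µCi on day 7, 2806 at 215 µCi on day 2, 706 and 10 for the activity trend on days 3 and 7, 3429 for the differences between days and 1 for the controls across days. The largest array cluster alone, with fewer arrays, gave 1721 and 5090 for all injected mice on days 5 and 14, 1356, 30 and 2572 at 158 µCi on days 2, 5 and 14, 212 and 2809 at 191 µCi on days 5 and 14, 2191 and 3376 at 215 µCi on days 5 and 14, 1953 and 5189 at 259 µCi on days 5 and 14, 0, 1 and 1693 for the activity trend on days 3, 5 and 14, 1312 for day 14 minus day 2 and 1 for the controls across days. Filling blanks with the 1st percentile of their array gave 171 and 0 for the activity trend on days 3 and 7. Testing the 7942 probes without a blank, fewer than the whole table, gave 3624, 4359, 4324 and 5392 for all injected mice on days 2, 5, 7 and 14, 4347 at 158 µCi on day 14, 4390, 4101 and 3974 at 191 µCi on days 2, 7 and 14, 3489, 3143 and 4132 at 215 µCi on days 5, 7 and 14, 3495, 3229 and 5439 at 259 µCi on days 5, 7 and 14 and 0 for the activity trend on day 7. Where these trend counts were 0 in limma, 1997 and 1322 probes on day 3 (1 day, largest cluster) and 1005 and 547 on day 7 (filled blanks, probes without a blank) had an unadjusted p under 0.05. On day 7 the 72 slopes from the arrays of that day were 9 rising and 63 falling, and the 19 with array weights 13 rising and 6 falling, where all 3 rose before.

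Scaling moved the division between directions. A common median raised the median difference over all probes by up to 0.17 in the day comparisons, and quantile normalization changed it by -0.19 at most. Arrays carry no read depth; dim probes limited precision, with 15.4% of values blank in the dimmest 10% of probes against 0.0554% in the brightest.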

Other observations

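The array clusters behind some paragraphs here were defined, and the tests that use them chosen, only after the result was seen. The splits of the arrays were planned before, except those for the differences between days.

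Labels were exchanged between arrays in 99 further splits for each count, within days except for the controls across days. For injected against control mice, the real split alone gave as many probes (1 of 100 on each day). The highest other counts were 2340 against 5530 on day 2, 108 against 6235 on day 3, 9 against 6771 on day 5, 2 against 6834 on day 7 and 3218 against 9251 on day 14. Chance is unlikely for these.

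Exchanging the arrays of 1 activity and the controls of 1 day gave lower counts too, apart from 2 comparisons on day 5. At 158 µCi the highest other counts and the real ones were 1292 against 2445 on day 2, 1746 against 2585 on day 3, 3475 against 2708 on day 5, 531 against 2721 on day 7 and 4838 against 7048 on day 14. For 191 µCi they were 6131 against 6669 on day 2, 5164 against 7569 on day 3, 4204 against 3741 on day 5, 5936 against 6346 on day 7 and 5560 against 6280 on day 14. With 215 µCi the pairs were 1475 against 1698 on day 2, 1981 against 2769 on day 3, 4163 against 5525 on day 5, 3765 against 4859 on day 7 and 5166 against 6487 on day 14. Mice given 259 µCi had 2767 against 3203 on day 2, 2319 against 3427 on day 3, 3539 against 5324 on day 5, 2897 against 5112 on day 7 and 7596 against 9255 on day 14. Several of the highest splits exchanged only 1 array each way, as at 158 µCi on day 14, and so kept much of the real difference. On day 5, 3 of 100 splits gave as many as the real one at 158 µCi and 2 of 100 at 191 µCi, and the real split alone did in the other 18 comparisons. All 20 met the bar fixed beforehand, a share under 0.05, which makes chance unlikely but does not exclude it. At these 2 the bar was met narrowly, since other splits gave more probes than the real one. The splits were drawn without regard to the clusters. The split with 3475 probes at 158 µCi set 5 arrays of cluster 3 and 1 of the largest cluster against 5 of the largest and 1 of cluster 2, so it followed the clusters. At 191 µCi, the split with 4204 probes set 4 arrays of the largest cluster and 2 of cluster 2 against 4 of the largest and 2 of cluster 3. The real 191 µCi and control groups of day 5 were divided over the clusters in the same way. On day 7, the split with 5936 probes at 191 µCi exchanged 1 array each way. It was also divided over the clusters like the real groups of that day. With the cluster as a block, 3882 probes were called at 158 µCi and 4297 at 191 µCi on day 5. The block kept 2614 of the 2708 calls at 158 µCi and 2981 of the 3741 at 191 µCi, with median differences of 1.01 against 1.10 and 0.87 against 1.03. In the largest cluster alone, with 2 arrays at 158 µCi and 4 at 191 µCi, the counts were 30 and 212, and the median differences 0.71 (median SE 0.46, against 0.33 in all arrays) and 0.67 (0.36 against 0.31). These medians are over probes called in all arrays, those of the largest cluster included, which favours differences in the same direction. They are therefore no independent evidence against the clusters. Most calls stayed with the block, in a fit to the same arrays, which argues against the clusters as the whole cause. How much they added stays open.

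For the activity trends, the 4 activities were exchanged among injected mice. The real split alone gave as many on day 14 (2895 against 1597) and over all days (2804 against 2). Chance is unlikely for these. On day 7 it did too (3 against 1), and the cluster block kept all 3. They were 0 in limma with filled blanks or among probes without a blank (1005 and 547 at an unadjusted p under 0.05), and the arrays of that day alone gave 9 rising and 63 falling, so the slopes of day 7 stay uncertain. On day 3, 2 of 100 splits gave as many as the real 112, with 266 at most. That share is under 0.05. When only the arrays of that day or of the largest cluster were fitted, 0 probes remained in limma (1997 and 1322 at an unadjusted p under 0.05). The median slope of the 112 was 1.58 in all arrays (median SE 0.40), 1.58 by construction in those of the day (0.42) and 1.28 in the largest cluster (0.51). The cluster block kept 112 of 112 and gave 706, array weights gave 1244 and filled blanks 171, so the number of calls depended on the fit. On days 2 and 5 the real count was 0 in limma (401 and 2765 probes at an unadjusted p under 0.05), so all 100 splits gave as many, with up to 347 on day 2 and 2041 on day 5. The median over the other splits was 0 on both days. Splits with so many more calls than the real one may point to a structure among the arrays, which was not tested. For the control groups across days, the real count was also 0 (1357 at an unadjusted p under 0.05), all 100 splits gave as many, and 9 probes were the most.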
